A study of Mus musculus with 2 samples.

How the data were processed

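Omental tumours of mice carrying KPCA ovarian cancer cells and given chemotherapy were measured by droplet single-cell RNA sequencing (10x Genomics). Per the labels, immune cells without B cells, cancer cells and fibroblasts were sorted from the tumours of 3 mice per group and pooled, whereas the cell type field names only CD45+CD19- immune cells. The deposited values are raw UMI counts per gene and cell from Cell Ranger 9.0.0, per the file headers, with every barcode at 500 UMIs or more. The submitters' processing notes list Seurat 5 and the genome build mm10, and state neither the annotation release nor whether introns were counted. There are 2 libraries and 32285 genes per library. The library labelled IL1bKO is batch 1 and the WT library batch 2, so batch and genotype cannot be separated.

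Cells with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, 14803 and 14488 in the library labelled IL1bKO and the WT library. Scrublet at an expected doublet rate of 10% called 456 (3.08%) and 400 (2.76%) of these as doublets, which were left out, leaving 14347 and 14088 cells. Counts scaled to 10000 per cell and logged, restricted to 2000 variable genes, gave 30 principal components, 15 neighbours per cell and 22 Leiden clusters at resolution 1, both libraries together. Each cluster was named after the highest scoring of the marker lists. Of the 28 lists fixed, those of CD4, CD8 and regulatory T cells were used only to label clusters already named T cell. The name was withheld when fewer than 3 markers were detected, when its 10 leading genes were markers of another class, or when its depth was low and no marker of its own was among them. Cluster 9 stayed unnamed. Clusters with at least 100 CPM of Ptprc counted as immune, 6437 and 5659 cells. Names are written X-like, since they rest on RNA alone.

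Counts were summed over the cells of a class in each library and scaled to CPM, UMIs per 1000000 UMIs of the class. The log2 ratio of the library labelled IL1bKO over WT has an exact conditional binomial interval, a CPM an exact Poisson interval and a share of cells an exact Clopper-Pearson interval, all at 95%. Intervals cover counting error only. Each genotype has 1 library, so no test, p-value or standard error was made, and no paired analysis was possible because each group is 1 library. For 23 gene lists, the median log2 ratio of members with at least 30 UMIs was ranked among 10000 random lists of the same size matched in 20 bins of mean expression. Named genes are, per class, the 10 highest and 10 lowest log2 ratios with an interval that excludes 0. They needed at least 50 CPM in 1 library, at least 30 UMIs over both, and a class CPM of at least 1 over 10 of the gene's highest class CPM. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes and unnamed gene models were left out, and list members could be named if among the 2 highest or 2 lowest of their list. Shares of cells with a UMI were also taken after thinning each cell to 1000 UMIs. Gene positions come from the GENCODE vM21 annotation, matched by Ensembl gene ID.

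The filters, lists, markers, comparisons, rule for named genes and 14 alternatives were fixed before the data were examined. The alternatives changed the cell filters, doublets, clustering, cell naming, variable genes, scaling, weighting of cells, depth, free RNA and the CPM minimum. After the data were seen, 5 more were added: leaving out droplets with at least 3 UMIs of 10 T cell marker genes, each neutrophil cluster alone, leaving out B-like and plasma-like cells from the denominator, and weighting cancer clusters equally. The description of mesothelial-like cells and the choice of which lists and list members to report were also made then. The named genes and lists of B-like and plasma-like cells were not described, since the sort aims to leave B cells out and their WT droplets held RNA of neutrophils and T cells. Free RNA, estimated from S100a8 and S100a9 in T-like cells, came to 92.3 and 227 UMIs per cell, 2.12% and 4.54% of the UMIs of a T-like cell. The estimate takes every such UMI as free RNA. S100a8 had a UMI in 2.625% and 2.17% of T-like cells, so its UMIs were not spread over more cells in WT. The higher WT estimate may therefore rest on few droplets, and it does not show more free RNA in WT.

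The intervals were computed on simulated data for a macrophage and a neutrophil setting. They covered the true ratio of 95.6% of unchanged genes in both. A simulated log2 change of 1 was found with its sign and an interval without 0 in 87.1% and 82.8% of changed genes. One of 0.5 was found in 73.1% and 52.2%. These rates speak to counting error only. Spread between mice or batches cannot be estimated from 1 library per genotype, so the rates do not show how the intervals perform under such spread. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.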

Results

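Single-cell RNA was measured in omental tumours of chemotherapy-treated mice carrying KPCA cells, a mouse ovarian cancer line. The omentum is the fat apron of the abdomen, to which ovarian cancer often spreads. The series holds 2 droplet libraries, each pooled from 3 mice: 1 titled IL1bKO, an Il1b knockout, and 1 titled WT, wild type. Interleukin 1 beta, the product of Il1b, is a cytokine that drives inflammation and draws in neutrophils, and the comparison asks how the cells of the treated tumour differ when it is missing. The library labelled IL1bKO held 15227 barcodes and 245479211 UMIs (unique molecular identifiers, 1 per captured RNA molecule), with a median of 14412 per barcode. The WT library held 14771 barcodes and 248012869 UMIs, with a median of 17209. After filters, 14347 and 14088 cells were kept. With 1 library per genotype there is no replicate check and no test: every interval is a 95% interval that covers counting error only. The genotype field of the labels reads wild type for both libraries, so the knockout rests on the title alone, and the batch labels (1 for IL1bKO, 2 for WT) coincide with it. Differences are therefore given between the library labelled IL1bKO, always first, and the WT library, as log2 ratios of IL1bKO over WT. RNA levels are in CPM, UMIs per 1000000 UMIs summed over the cells of a class.

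Il1b (gene ID ENSMUSG00000027398), the targeted gene, lies on chromosome 2 from 129364570 to 129371139 on the minus strand (mm10) and has 7 exons in its transcript Il1b-201. Il1b RNA was lower in the library labelled IL1bKO in each class compared, and it was far from absent. Its highest level was in a Csf3r-high cluster of neutrophil-like cells, at 6619 against 13267 CPM in the library labelled IL1bKO against WT (log2 -1.003, interval -1.04 to -0.96). A second, Camp-high cluster of neutrophil-like cells, marked by genes of immature granules, held 220.1 against 1474 CPM (log2 -2.74, interval -2.93 to -2.56). Over both clusters the ratio was -1.75, interval -1.79 to -1.72, a value that weights the deeper Camp-high cells more. Macrophage-like cells held 663 against 1757 CPM (log2 -1.41, interval -1.45 to -1.36) and dendritic-cell-like cells 560.4 against 1027 CPM (log2 -0.87, interval -0.97 to -0.78). In further classes the levels were 2.58 against 24.5 CPM in T-like cells, 0.731 against 18.3 CPM in NK-like cells, 1.18 against 31.2 CPM in fibroblast-like cells, 5.15 against 19.3 CPM in mesothelial-like cells, 1.54 against 3.55 CPM in cancer-like cells, 2.33 against 222 CPM in B-like cells and 7.21 against 207 CPM in plasma-like cells. In WT, 149 Il1b UMIs lay in 5 of 161 B-like cells and 312 in 12 of 88 plasma-like cells. A further 81 lay in 7 of 124 fibroblast-like cells and 32 in 5 of 436 NK-like cells. T-like cells held 237 in 64 of 1932 cells, mesothelial-like cells 496 in 58 of 1174 and cancer-like cells 629 in 273 of 7115. These levels rest on a small share of droplets and cannot be read as expression by the class. Fibroblast-like cells held 4 Il1b UMIs in the library labelled IL1bKO. Their log2 ratio was -4.73, but -2.35 with doublets kept and -1.56 with each cell named by its own score. That last naming gave 954 and 1127 fibroblast-like cells in place of 218 and 124, so its value rests largely on other cells. With each cell thinned to 1000 UMIs, 88.7% (85.5 to 91.4) of Csf3r-high neutrophils in the library labelled IL1bKO had an Il1b UMI against 94.6% (92.8 to 96.00) in WT, and 75 and 103 shallower cells were left out. The unthinned shares were 89.9% and 94.4% at median depths of 1841 and 1793 UMIs. The background share in T-like cells, at medians of 3930 and 4054 UMIs, was 0.0844% and 1.68% after thinning. The deleted part of the gene is not given in the sources used here, and a 3' tag outside a deletion does not check a knockout.

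**Figure D1:**
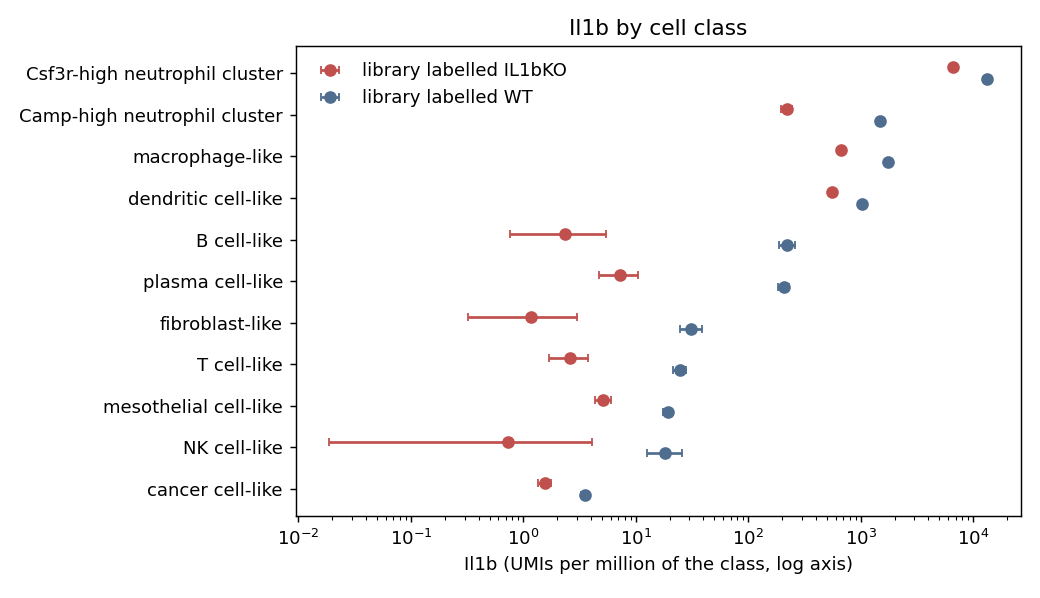
Il1b in CPM of each class (log axis) in the library labelled IL1bKO (red) and the WT library (blue), with points for summed counts and bars for exact 95% Poisson intervals. Csf3r-high neutrophils sit highest in both libraries, at 6619 against 13267 CPM, and each class lies lower in the library labelled IL1bKO.

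To compare the immune cells, each class was taken as a share of all immune cells, because cancer cells and fibroblasts were sorted too and pooled with them. Neutrophil-like cells made up 10.6% (9.90 to 11.4) against 18.3% (17.3 to 19.4) (log2 -0.78, interval -0.93 to -0.64). The Csf3r-high cluster was at 8.47% (7.80 to 9.17) against 16.4% (15.5 to 17.4) and the Camp-high cluster at 2.17% (1.83 to 2.56) against 1.89% (1.55 to 2.28). Camp-high cells were 20.4% against 10.3% of neutrophil-like cells. NK-like cells were lower, at 5.58% (5.03 to 6.17) against 7.70% (7.02 to 8.43), as were dendritic-cell-like cells, at 3.81% (3.35 to 4.30) against 4.82% (4.28 to 5.42). The log2 ratio of the dendritic-cell-like share was -0.22 (-0.47 to 0.04) without B-like and plasma-like cells in the denominator and -0.0611 (-0.35 to 0.23) without droplets holding T cell marker UMIs, intervals that include 0. Macrophage-like cells were at 19.4% (18.5 to 20.4) against 17.7% (16.7 to 18.7) (log2 0.14), and their log2 ratio was 0.49 (0.35 to 0.64) without droplets holding T cell marker UMIs and 0.55 (0.41 to 0.69) with each cell named by its own score. That naming counted 9162 and 8627 cells as immune, against 6437 and 5659 in the main setting. In a sort described as leaving out B cells, B-like cells were higher, at 9.06% (8.37 to 9.78) against 2.85% (2.43 to 3.31), and so were plasma-like cells, at 3.34% (2.91 to 3.81) against 1.56% (1.25 to 1.91). The NK-like order turned when each library was clustered alone, a setting that left 0 and 1043 cells unnamed.

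T-like cells were 37.3% (36.1 to 38.5) against 34.1% (32.9 to 35.4) of immune cells. This order turned with doublets kept, where 905 and 642 cells stayed unnamed. It also turned at a finer clustering, where 2303 and 1299 did, not all of them immune cells. A further cluster scored highest for T cell markers but had none among its leading genes, which included Fgf13, Klrk1 and Lef1; it stayed unnamed, at 10.9% (10.1 to 11.6) against 12.9% (12.1 to 13.8). T-like cells and that cluster together were 48.1% (46.9 to 49.4) against 47.1% (45.8 to 48.4). Within T-like cells, CD4-like cells were 13.1% against 9.49% of immune cells, CD8-like cells 19.5% against 21.4% and regulatory-T-like cells 4.68% against 3.29%. No cluster was named monocyte. Shares of this kind also rest on the sort, on the depth and on the minimum of 500 UMIs per cell, against medians of 1999 and 1882 UMIs in neutrophil-like cells.

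**Figure D2:**
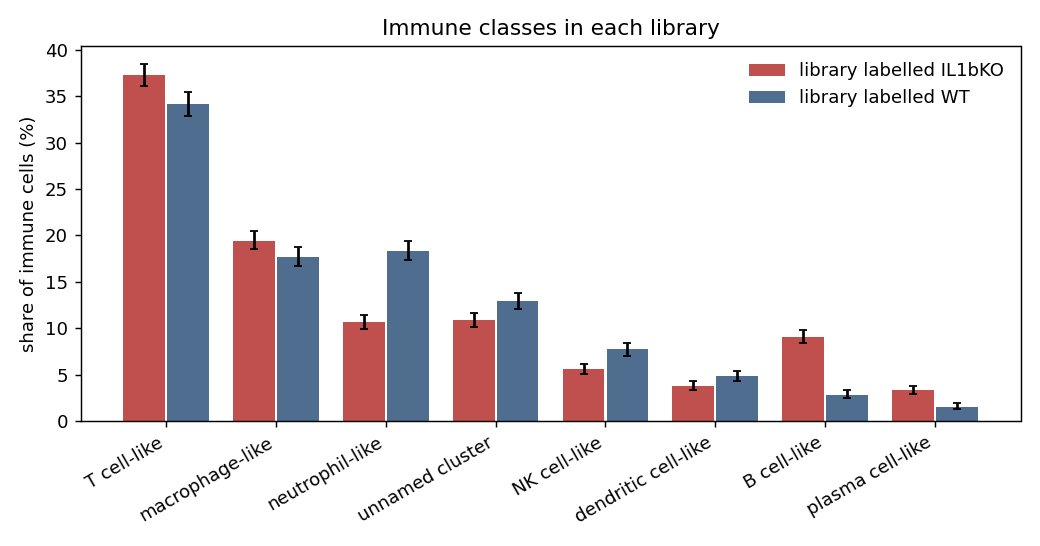
Share of immune cells in percent for each class in the library labelled IL1bKO (red) and the WT library (blue), with exact 95% binomial intervals for counting error only. Neutrophil-like cells stand at 10.6% against 18.3%, and B-like cells at 9.06% against 2.85%.

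Droplets of some myeloid and plasma-like classes also held T cell RNA, and did so unequally in the 2 libraries. Droplets with at least 3 UMIs of T cell markers made up 11.4% (9.65 to 13.2) against 34.8% (31.8 to 37.8) of macrophage-like droplets, 13.1% (9.11 to 17.9) against 32.6% (27.1 to 38.5) of dendritic-cell-like droplets and 8.37% (5.04 to 12.9) against 35.2% (25.3 to 46.1) of plasma-like droplets. In cancer-like droplets, which are deeper, the shares were 0.701% against 0.478%, in mesothelial-like droplets 1.55% against 1.96% and in neutrophil-like droplets 0.438% against 1.35%. Values of macrophage-like and dendritic-cell-like cells are therefore also given without these droplets, a setting chosen after the data were seen. The list of immediate early and dissociation genes, a sign of handling, also differed by class: 11 of 13 were higher in macrophage-like cells (median 0.50) and 8 of 13 in T-like cells (median 0.23, percentile 98.77), while 9 of 13 were lower in NK-like cells (median -0.32) and 12 of 13 in mesothelial-like cells (median -0.39, percentile 0.03). For each list given with its count of genes, the median log2 ratio lay beyond all of 10000 random lists matched for size and mean expression, unless its percentile among them is given.

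In neutrophil-like cells, the genes highest in the library labelled IL1bKO against WT were genes of DNA replication and division, and those lowest included Il1b and interferon-induced genes. The replication gene Rrm2 stood at 65.8 and 12.2 CPM (log2 2.43), and Clspn (2.62), Cip2a (2.29), Spc25 (2.12), Kif15 (2.03), Pclaf (1.94), H2afx (2.11), Hist1h2ae (1.94), Hist1h1b (1.88) and Dnmt1 (1.87) were also higher. Of the cell cycle list, 12 of 12 measured genes were higher (median 1.61). The median of the same genes was 0.80 with doublets kept and 0.54 (-0.33 to 0.89) in Csf3r-high cells alone, an interval that includes 0. Of the granulocyte precursor and granule list, 14 of 14 were higher (median 1.10), led by the granule protease gene Ctsg (1.48) and by Chil3 (1.44). Lower genes were Oasl1 (-1.47), Cxcl10 (-1.47), Zfp263 (-1.37), Elmod3 (-1.24), Egln3 (-1.22), Ston2 (-1.18), F3 (-1.17) and Smad3 (-1.15) and Acod1 at 2664 and 5930.2 CPM (-1.15), which makes the metabolite itaconate. Of the RNA quality list, which holds mitochondrial genes, Malat1 and Neat1, 8 of 10 were higher (median 0.42, percentile 98.29), with Malat1 at -0.43 and Neat1 at -0.52. With each cell named by its own score, that median was -0.0683, where its interval, like the main one, included 0. In the type I interferon list, 16 of 17 genes were lower (median -0.75), among them Rtp4 (-1.26), and in the interferon gamma list 13 of 16 (median -0.50, percentile 0.01). So were 17 of 18 of the IL-1 and NF-kB list (median -0.62), with Cxcl3 at -0.99, and 14 of 16 of the tumour-associated neutrophil list (median -0.44, percentile 0.59), with the PD-L1 gene Cd274 at -0.94 and Ccl3 at -0.79.

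Camp-high cells had unequal weight in these sums, at 20.4% and 10.3% of the class. The granule list had a median -0.02, percentile 21.945, in Csf3r-high cells alone (3 of 7 measured genes higher) and a median 0.24, percentile 86.9, in Camp-high cells alone (11 of 14 higher), and so stood apart from random lists in neither. The RNA quality list stood at 0.13 (percentile 84.475) in Csf3r-high and at 0.0913 (percentile 57.305) in Camp-high cells alone. In Csf3r-high cells alone, the IL-1 and NF-kB list stood near 0 (median 0.02, percentile 33.9), as did the tumour-associated list (median 0.06, percentile 52.925), with Ccl3 at -0.04 and Cd274 at -0.18. The type I interferon list there had a median -0.16, percentile 0.17, and the interferon gamma list a median 0.01, percentile 10.59. Hist1h1b (-1.11, interval -2.44 to 0.04) and Dnmt1 (-0.11, interval -1.81 to 1.41) were not higher in them, with intervals that include 0. The other named higher genes stayed above 0 under each alternative that gave a value, their lowest values running from 0.49 (H2afx) to 1.54 (Rrm2). Cxcl10 (-1.11), Ston2 (-0.90), Egln3 (-0.49) and Acod1 (-0.43) remained lower in Csf3r-high cells. In Camp-high cells alone, 11 of 12 cell cycle genes were higher (median 0.76, percentile 99.99), 14 of 16 genes of the IL-1 and NF-kB list were lower (median -1.03), and Cxcl3 (-2.24) and Cd274 (-2.23) were among the lower genes. Cxcl10 was higher, at 1.45 on 33 and 7 UMIs. The interferon gamma list, with the members measured in the whole class, stood at 0.08 (-0.88 to 0.78) in Camp-high cells.

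In macrophage-like cells, the lists of resident omental macrophage genes and of MHC class II presentation were higher in the library labelled IL1bKO. The highest ratio among the named genes was that of Retnla (gene ID ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, mm10), a marker of alternative activation, at 556 and 4.17 CPM (log2 7.06, interval 6.59 to 7.57). After thinning to 1000 UMIs, 9.65% of macrophage-like cells had a Retnla UMI against 0.407%, with 0.0844% and 0 of 1904 T-like cells (interval up to 0.194%) as background. Unthinned, the macrophage shares were 16.2% and 2%. The growth factor gene Igf1 (2.39), the apoptotic-cell receptor gene Mertk (1.41) and Adgre1, which encodes F4/80 (1.41), were also higher, with Zbtb16 (2.14), Ly6i (1.87), Tmem176b (1.64), Agmo (1.63), Tmem176a (1.59) and Fkbp5 (1.56). All 11 measured genes of the MHC class II list were higher (median 0.74), with H2-Aa at 1760 and 872 CPM (1.01) and H2-Eb1 at 0.94. In the resident omental macrophage list, 11 of 13 were higher (median 0.91), Lyve1 the most (1.98), while Pf4 (-0.64) and F13a1 (-0.19) were lower. In the lipid-associated list, 10 of 18 were higher (median 0.36, percentile 99.95), Chil3 (1.18) and Apoe (1.10) at one end and Spp1 (-1.43) at the other.

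Of 11 measured neutrophil chemoattractant and growth factor genes, none was higher in macrophage-like cells of the library labelled IL1bKO (median -1.10). That list holds S100a9 (-4.07) and S100a8 (-2.82), which are neutrophil markers too, and 10 of 13 genes of the circulating neutrophil list were also lower (median -0.54). In the IL-1 and NF-kB list, 11 of 19 were lower (median -0.32), Cxcl3 at -1.25, while Saa3 (0.78) and Icam1 (0.48) were higher. Of the hypoxia and glycolysis genes, 14 of 16 were lower (median -0.45), with Adm at -1.39 and Ero1l at -0.79. The genes lowest by ratio were Gzmb (-3.05), Rgs16 (-2.32), Nkg7 (-2.21), Ctsw (-2.17), Cd3d (-2.11), Ptprcap (-2.04), Gimap4 (-2.02) and Cd8a (-2.02), most of them known from lymphocytes, and the chaperone genes Hsph1 (-2.08) and Hspa1b (-2.01); the cytotoxicity list had 14 of 14 genes lower (median -1.52). Without droplets holding T cell marker UMIs, Gzmb stood at -0.11, Nkg7 at -0.41, Hsph1 at -0.95 and Ptprcap at 0.32. Cd8a (-0.26) and Cd3d (-0.59) are among the 10 genes counted in choosing these droplets, so their values partly follow from leaving them out. Ctsw (-2.17), Rgs16 (-2.02), Gimap4 (-1.61) and Hspa1b (-1.60) stayed low without them. Retnla (6.74), Mertk (1.27), the MHC class II list (0.68) and the resident list (0.69) kept their direction, and the lipid-associated list stood at 0.20 (percentile 96.77).

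Dendritic-cell-like cells of the library labelled IL1bKO had more RNA of Mrc1, the mannose receptor gene (182 and 49.2 CPM, log2 1.89), and of the conventional dendritic cell gene Cd209a (1.06). Over the alternatives, Mrc1 ranged from 0.61 to 2.07. Slco5a1 (1.28), Fgfr1 (1.25), Fkbp5 (1.15), Dscaml1 (1.03), Ear2 (1.01), Syn3 (1.00), Dock5 (0.95) and Pid1 (0.94) were higher as well. Interferon-induced genes were lower: 11 of 15 of the type I interferon list (median -0.37, percentile 0.04) and 13 of 17 of the interferon gamma list (median -0.21, percentile 0.05), with Rsad2 at 12.8 and 78.8 CPM (-2.63), Ifit2 (-2.07), Cxcl10 (-1.12) and Gbp4 (-1.02). Ifit1 had 1 UMI against 55 (log2 -5.48, interval -10.81 to -2.94). Of the cell cycle genes, 10 of 12 were lower (median -0.59), among them Cdk1 (-1.24) and Rrm2 (-1.08). Of the MHC class II list, 9 of 11 were higher (median 0.22, percentile 99.44), H2-Aa at 0.33. The other lowest genes were the lymphocyte genes Gzmb (-3.42), Ctsw (-2.48), Nkg7 (-2.47), Sh2d2a (-2.15), Gimap6 (-2.07), Cd3g (-2.05) and Cd3d (-2.05) and Hsph1 (-2.22), and the cytotoxicity list had 13 of 13 genes lower (median -1.99). Without droplets holding T cell marker UMIs, the interferon gamma list stood at -0.34, the type I list at -0.31 (percentile 0.135), and the MHC class II list no longer stood apart, at 0.15 (percentile 79.95). Among the lymphocyte genes, Nkg7 (-2.89) and Gzmb (-1.31) then stayed low, Cd3d stood at -0.31 and Gimap6 at 0.69, and Ctsw, Sh2d2a and Cd3g had no value. Cd3d and Cd3g are among the genes counted in choosing the droplets left out. With each cell named by its own score, Fgfr1 stood at -0.0690, over 1479 and 1578 dendritic-cell-like cells in place of 245 and 273.

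In T-like cells of the library labelled IL1bKO, the lists of naive and memory and of T helper 17 genes were higher and the list of cell cycle genes was lower. Tnf stood at 132 and 44.8 CPM (log2 1.56) and the interleukin 7 receptor gene Il7r at 725 and 282 CPM (1.36). Nr4a3 (1.13), Tmem106b (1.08), Fkbp5 (1.07), Pde11a (1.06), Tnfsf11 (1.01), Ccnd3 (1.01), Cd40lg (0.95) and Tgfbr3 (0.92) were higher too; Cd40lg and Tnfsf11 were also leading genes of the CD4-like cluster, which held more of the T-like cells in that library. All 7 measured genes of the T helper 17 and gamma delta 17 list were higher (median 0.84, percentile 99.99), Il23r (17.02 and 4.76 CPM, 1.84) and Blk (1.30) the most. Of the naive and memory list, 9 of 11 were higher (median 0.44, percentile 99.99), with S1pr1 at 0.97. None of the 12 cell cycle genes was higher (median -0.89), with Birc5 at -1.25 and Rrm2 at -1.22, and Hist1h2ae (-1.47), Hist1h3c (-1.24), Hist1h1b (-1.18) and Pclaf (-1.22) were lower with them. A cluster of T-like cells with Neil3 and Hist1h1a among its leading genes held 46 against 121 cells, at a median of 8134 UMIs. Among the lowest were the chaperone genes Hspa1b (-2.41), Hspa1a (-2.17), Hsph1 (-1.66), Dnajb1 (-1.40) and Hsp90aa1 (-1.16), with Phlda1 (-1.46). The cytotoxicity list had 7 of 14 genes higher (median -0.05, percentile 1.98), with Fasl at 0.50 and Gzmb at -0.86, and the exhaustion list 8 of 14 (median 0.08, percentile 44.07), with Rgs16 at -0.57. Of the hypoxia and glycolysis genes, 13 of 15 were lower (median -0.34). With doublets kept, the T helper 17 list stood at 0.06 and Il23r at -0.02.

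NK-like cells of the library labelled IL1bKO also had more Il7r (961 and 311 CPM, log2 1.63) and less RNA of the killing machinery. Of the genes of the cytotoxicity list, 11 of 13 were lower (median -0.28, percentile 0.01), among them the pore-forming protein gene Prf1 (-0.88), Gzmb (-0.80) and, outside the list, the granzyme gene Gzmc (-1.39). Of the exhaustion and checkpoint genes, 11 of 14 were lower (median -0.35), Havcr2 (-1.47) and Rgs16 (-1.14) the most, and 10 of 11 naive and memory genes were higher (median 0.31, percentile 99.83). Higher genes further included Cntn1 (2.33), Large1 (1.43), Donson (1.20), Arhgap31 (1.12), Ccdc171 (1.10), Pik3ip1 (1.04), Xrcc4 (1.03), Ccr7 (1.02) and S100pbp (0.95). Other low genes were Hspa1a (-2.61), Hspa1b (-2.48), Hsph1 (-1.83), Irf4 (-1.76), Dnaja4 (-1.59), Tmem163 (-1.47), P4ha1 (-1.43), Dnajb1 (-1.40) and Rap1gap2 (-1.16). Over the alternatives, Dnaja4 reached -0.07, Tmem163 -0.14 and, among the higher genes, Large1 0.28. The T cell marker Cd3g had a UMI in 17.7% and 15.9% of NK-like cells after thinning and in 46.2% and 42.7% unthinned, at median depths of 3503 and 3660.5 UMIs. In neutrophil-like cells, at medians of 1999 and 1882 UMIs, it did so in 0.165% and 0.429% after thinning and in 0.584% and 0.771% unthinned. Thinning left out 9 and 3 NK-like cells. When each cell was named by its own score, the cytotoxicity list stood at 0.18, the exhaustion list at 0.19, Havcr2 at 0.29, Ccr7 at -0.34 and Irf4 at 0.10.

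Mesothelial-like cells, which line the omentum, were found in number although the labels do not name them. Their comparison was therefore chosen after the data were seen. They numbered 1549 and 1174, but 599 and 538 at resolution 2 and 792 and 324 with each cell named by its own score. The cytokine and chemokine genes that IL-1 is known to induce were lower in the library labelled IL1bKO: 17 of 19 of the IL-1 and NF-kB list (median -0.78) and all 10 measured neutrophil chemoattractant and growth factor genes (median -1.65). Genes of other cell types were lower in the same droplets too: 7 of 8 measured genes of the circulating neutrophil list (median -0.62, percentile 0.05) and 8 of 8 of the cytotoxicity list (median -0.90, percentile 0.01). Cxcl1, a neutrophil chemoattractant, stood at 216 and 649 CPM (log2 -1.59), the monocyte chemoattractant Ccl7 at 131 and 399 CPM (-1.61), Il6 at -1.97 and Lif at -1.72. None of the 16 hypoxia and glycolysis genes was higher (median -0.92), with the hexokinase gene Hk2 at -1.67 and Ankrd37 at -1.37, and 11 of 12 cell cycle genes were lower (median -1.10), Rrm2 (-1.92) and Ccnb1 (-1.69) the most. Ctla2a (-2.96), Hmox1 (-1.84), Olr1 (-1.83), Serpinb2 (-1.63), Gadd45g (-1.61), Phlda1 (-1.59) and Hsph1 (-1.55) were lower. Higher genes were Hmgcs2, of ketone body synthesis (203 and 39.1 CPM, 2.37), the mesothelial gene Muc16 (1.38), Igfbp5 (2.16), Zbtb16 (1.91), Pde7b (1.74), Lrp2 (1.44), Itih5 (1.42), Pcdh15 (1.40), Dock3 (1.40) and Kcnab1 (1.37). The median log2 ratio over all genes of this class, relative to which these ratios can be read, was 0.12. Muc16 reached 0.40, Kcnab1 0.33 and Ctla2a -1.39 over the alternatives, all with their direction kept.

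Fibroblast-like cells (218 and 124 cells) also differed in genes of inflammation. Lower in the library labelled IL1bKO were 14 of 16 genes of the IL-1 and NF-kB list (median -0.87) and 13 of 14 of the inflammatory fibroblast list (median -0.70). Cxcl1 stood at 94.05 and 529 CPM (log2 -2.49), and Cxcl2 (-3.31), Cxcl5 (-2.65), Ccl2 (-2.40) and Ptx3 (-2.37) were lower too, while the complement gene C3 was at 0.26. The 8 measured chemoattractant and growth factor genes were all lower (median -2.57), but 2 of them are S100a8 (-3.35) and S100a9 (-4.88), genes of neutrophils. Of the contractile and matrix genes, 10 of 13 were lower (median -0.73), with Acta2 at -1.59, as were 13 of 15 hypoxia and glycolysis genes (median -0.59), with Hilpda at -1.77. Other lower genes were H19 (-4.72), Hspa1a (-2.18), Hspa1b (-2.02), Hsph1 (-1.91), Ppp2r2b (-1.85) and Cyp51 (-1.84). Higher genes were the retinal dehydrogenase gene Aldh1a1 (318 and 66.7 CPM, 2.25), Itgbl1 (3.80), Mamdc2 (2.54), Fmo2 (2.39), Hmgcs2 (2.21), Gpnmb (2.20), Galnt15 (2.20), Tsc22d3 (2.14), Txnip (2.12) and Brinp3 (1.87). Clustered apart in each library, fibroblast-like cells had H19 at 2.41 and Acta2 at 0.10. Over the alternatives, Cxcl1 reached -1.29, Ccl2 -1.16, Cxcl5 -0.59 and, among the higher genes, Itgbl1 1.26, all with their direction kept.

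In cancer-like cells, the ratios of the named higher genes stayed under 1 on the log2 scale. The summed depth of the class was 163137382 and 177036655 UMIs, the highest of the classes. Chaperone genes were among the lowest in the library labelled IL1bKO: Hspa1b at 51.5 and 295 CPM (log2 -2.52), Dnajb1 (-1.64), Hspb1 (-1.60), Hsph1 (-1.59) and Cryab (-0.83). None of the 18 interferon gamma genes was higher (median -0.33), with Gbp4 at -0.68 and Ido1 at -0.77. Of the type I interferon genes, 16 of 18 were lower (median -0.42), with Isg15 at -0.87, Ifit1 at -2.01 and Rsad2 at -1.47. Of the hypoxia and glycolysis genes, 15 of 16 were lower (median -0.42), Adm (-2.08) and Ankrd37 (-1.14) the most, as were all 12 cell cycle genes (median -0.31), with Mki67 at -0.42 and Ube2c at -0.47. P4ha1 (-1.12), Sprr1a (-1.03), Adamts1 (-0.81) and Rhob (-0.76) were lower too. Higher genes were the cyclin gene Ccnd3 (303 and 197 CPM, 0.62), Pknox2 (0.99), Emb (0.82), Fermt1 (0.71), Mid1 (0.67), Selenop (0.65), Nr4a1 (0.64), Ankrd33b (0.59), Atp1b1 (0.58) and Bace2 (0.58). The p53 list (median -0.02, percentile 5.175) had 7 of 15 genes higher, with Eda2r at -0.64, and the IL-1 and NF-kB list (median -0.06, percentile 0.14) 7 of 20. The largest of 7 clusters of cancer-like cells was cluster 1 in the library labelled IL1bKO (1604 against 1022 cells) and the cycling cluster 3 in WT (864 against 1491).

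**Figure D3:**
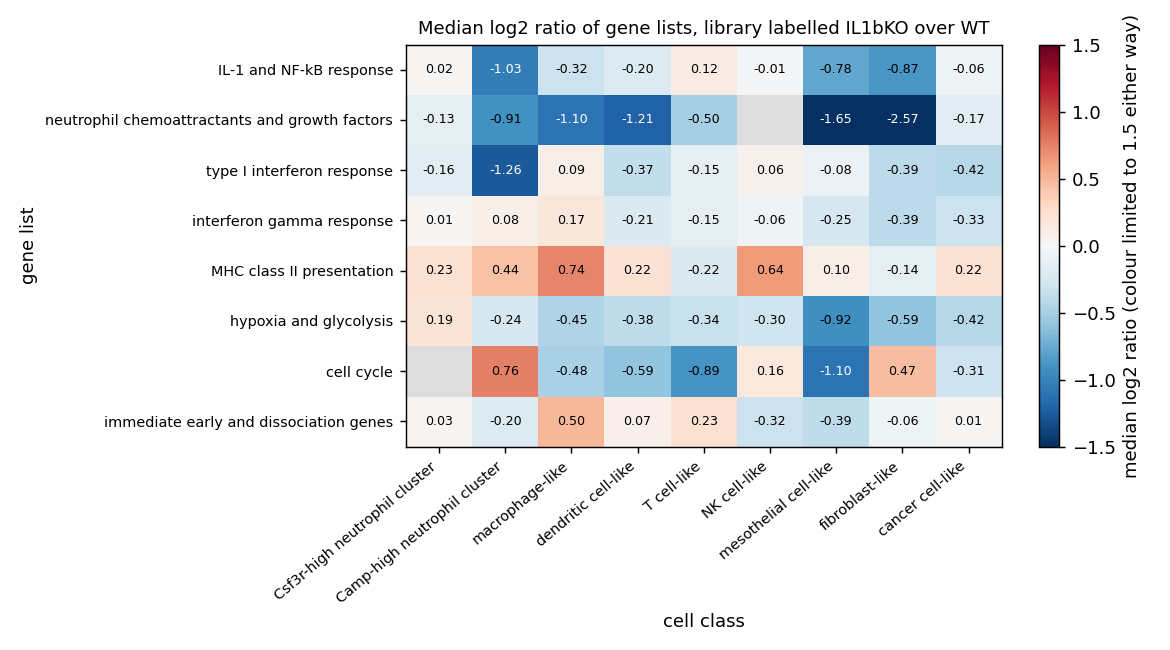
Median log2 ratio (library labelled IL1bKO over WT) of 8 gene lists (rows) in 9 cell classes or clusters (columns), blue for lower and red for higher in the library labelled IL1bKO, grey where under 5 members were measured; the colour scale ends at 1.5 either way. The chemoattractant list is lowest in fibroblast-like (-2.57) and mesothelial-like cells (-1.65), and the MHC class II list is highest in macrophage-like cells (0.74).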

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

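In this part, the tests on random doublets and on a lower heat shock response as a whole were chosen before their results were seen, and the other tests after. B-like cells were 9.06% of immune cells in the library labelled IL1bKO and 2.85% in WT, although the sort was to leave B cells out. Their share and Il1b level are in the report, while their named genes and fixed lists are not. Plasma-like cells, whose named genes and fixed lists are not in the report either, were 3.34% of immune cells in the library labelled IL1bKO and 1.56% in WT. Endothelial-like cells, which the labels do not name, were 1.03% of all cells kept in the library labelled IL1bKO (148 cells) and 0.114% in the WT library (16 cells).

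Il1b RNA was lower in the library labelled IL1bKO, yet plentiful in its Csf3r-high neutrophils. A mixture of wild-type cells with cells that hold no Il1b would need 52.8% of these neutrophils without an Il1b UMI at 1000 UMIs per cell, and 11.3% had none (upper bound 14.5%). Lower activation of the same cells as the whole cause, as far as the IL-1 and NF-kB list reads it, is argued against by that list. Its median log2 ratio in them was 0.0152 (-0.12 to 0.17) against -1.003 for Il1b. The tumour-associated list also stood near 0, but the type I interferon list, Egln3 (-0.49) and Acod1 (-0.43) were lower in these cells. Lower activation of a kind that the NF-kB list does not read stays open. That Il1b ratio could come from a transcript kept by the knockout allele, which cannot be told apart here from a library that carries working Il1b, since counts per gene hold no exon positions and the allele is not given. Batch coincides with genotype and stays open too.

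Droplets of macrophage-like cells held T cell marker UMIs 0.326 times as often in the library labelled IL1bKO as in WT. Free RNA is argued against, since only 0.478% of WT cancer-like droplets held such UMIs, although these are deeper. Random doublets at loading should meet all cell types alike, but with doublets kept the share in WT was 15.9 times higher in C1q-positive than in keratin-positive droplets (12.8 to 19.8), at 44.2% and 2.79%. Macrophage-like droplets with these UMIs were deeper, at medians of 9606.5 and 10659.5 UMIs against 6356 and 7075.5 in the class. Stuck cells would give this, but deeper droplets also reach 3 UMIs more easily. Uptake by macrophages would leave out plasma-like (8.37% against 35.2%) and B-like droplets (0.343% against 6.21%). For macrophage-like droplets, immune cells that stuck together before loading, or macrophages that took up T cells, remain possible and cannot be told apart, as batch and genotype coincide. With these droplets left out, Retnla, Mertk and the MHC class II list kept their direction in macrophage-like cells and the lymphocyte gene Ptprcap did not (0.32).

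The heat shock genes Hspa1a, Hspa1b, Hsph1 and Dnajb1 had a median log2 ratio under 0 in 10 of 10 classes, from -3.30 in B-like to -0.53 in neutrophil-like cells, though not in neutrophil-like cells thinned to 1000 UMIs (0.05). In T-like cells the median was -1.90 after thinning to 1000 UMIs. Thinning keeps each cell's expected proportions and only weights deep and shallow cells alike, so it cannot decide on a difference in depth. NK-like cells stood at -2.16 with only 4.005 CPM of Il1r1 in WT, so the lower level did not need high Il1r1 RNA. Low RNA does not show that the receptor is absent, so this cannot decide on IL-1 signalling within the same cell. A lower heat shock response as a whole stays open: 8 other chaperone genes lay under the 2.5th percentile of random lists in 4 of 10 classes, between the bounds set for and against it, and were higher in neutrophil-like cells (7 of 7 measured, median 0.83, percentile 98.62). Handling or batch could give such a pattern and cannot be told apart from genotype, because the batches and the genotypes coincide. Which of these holds was not decided.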

How the results depend on the processing

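Of the alternatives, 5 were chosen after the data were seen: the 2 neutrophil clusters alone, droplets with T marker UMIs left out, B-like and plasma-like cells left out of the denominator, and cancer clusters weighted equally. All values here are log2 ratios of the library labelled IL1bKO over WT. The neutrophil share kept its direction under 11 alternatives (-0.86 to -0.66), as did the B-like share under 10 (1.63 to 1.70), and Il1b was lower under each alternative that gave a value in the 8 classes tested, which leave out B-like and plasma-like cells. Of these classes, T, NK, mesothelial, fibroblast and cancer cells held Il1b in a small share of droplets, so their ratios cannot be read as expression by the class. Kept in direction under 14 alternatives each were the macrophage MHC class II list (0.67 to 0.80) and resident list (0.57 to 1.06), the mesothelial NF-kB (-0.94 to -0.76) and chemoattractant lists (-1.78 to -1.10) and the fibroblast NF-kB list (-1.03 to -0.53). Under 15, so were the cancer interferon gamma (-0.38 to -0.20) and hypoxia lists (-0.48 to -0.36). Among gene values, 2556 stayed within their interval, 649 left it and 16 changed direction; among list medians, 687, 41 and 6. A change of direction was counted only where the main interval left out 0, and 10 list medians whose main interval included 0 changed sign besides, all within 0.19 of 0. Medians here keep the list members measured in the whole class, whereas the report takes for a neutrophil cluster the members measured in that cluster.

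With doublets kept, the T share was -0.0688, Il1b in neutrophils -1.55 and in fibroblasts -2.35, the neutrophil cell cycle list 0.80 and NF-kB list -0.41, the T helper 17 list 0.0630 and Il23r in T cells -0.0244. At resolution 0.5, the T share was 0.0152, Il1b in T cells -2.48, the T cell cycle list -0.78 and H19 in fibroblasts 1.36. At resolution 2, the T share was -0.38, the T cell cycle list -0.60 and Il1b in mesothelial cells -1.11. With each library clustered alone, the T share was 0.52, the NK share 0.99, the T helper 17 list 0.43, Irf4 in NK cells 1.003, and H19 and Acta2 in fibroblasts 2.41 and 0.10. With 4000 variable genes, the T share was 0.0384, the T cell cycle list -0.80 and H19 in fibroblasts 1.35. The T cell cycle list was -0.81 at a maximum of 5% mitochondrial UMIs and -0.81 with the fixed lists left out of clustering, and Il1b in T cells -2.45 at stricter depth.

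With each cell named by its own score, the macrophage, NK and plasma shares were 0.55, -0.72 and 0.40. Il1b was then -1.60 in neutrophils, -1.30 in macrophages, -1.34 in dendritic cells, -1.56 in fibroblasts and -0.81 in cancer cells. The granule list was 1.54 and the NF-kB list -0.47 in neutrophils, the T cell cycle list -0.60 and the NK cytotoxicity list 0.18. Fgfr1 in dendritic cells was -0.0690, and Ccr7, Irf4 and Havcr2 in NK cells -0.34, 0.10 and 0.29. That naming changed the classes themselves, with 954 and 1127 fibroblast-like, 1479 and 1578 dendritic-cell-like and 2422 and 3055 cancer-like cells. The main setting had 218 and 124, 245 and 273, and 5995 and 7115. The values of these classes therefore rest partly on different cells.

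By the mean of each cell's CPM, Il1b was -1.14 in neutrophils, -1.52 in macrophages, -2.57 in T cells and -1.58 in mesothelial cells, and the T cell cycle list -1.10. The neutrophil NF-kB and interferon gamma lists were -0.16 and 0.0019. With cells thinned to 1000 UMIs, Il1b was -1.20 in neutrophils, -1.59 in macrophages, -1.06 in dendritic cells and -4.05 in T cells, the neutrophil NF-kB list -0.10, the T cell cycle list -1.16 and Eda2r in cancer cells 0.51. Il1b in neutrophils was -1.85 with the median gene ratio set to 0 and -1.84 with free RNA subtracted, and in cancer cells -0.37 with free RNA subtracted and -0.88 with cancer clusters weighted equally. The values with free RNA subtracted rest on the uncertain estimate described with the processing.

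Without droplets with T marker UMIs, the macrophage, dendritic and plasma shares were 0.49, -0.0611 and 1.52, Il1b was -1.64 in macrophages and -0.56 in dendritic cells, Ptprcap in macrophages 0.32 and Gimap6 in dendritic cells 0.69. Without B-like and plasma-like cells in the denominator, the macrophage and T shares were 0.26 and 0.25. In Csf3r-high neutrophils alone, Il1b was -1.003, and the granule, cell cycle, NF-kB, interferon gamma and tumour-associated lists of all neutrophils were 0.18, 0.54, 0.0152, 0.0140 and 0.0582; Hist1h1b was -1.11 and Dnmt1 -0.11. In Camp-high neutrophils alone, Il1b was -2.74, the granule, cell cycle, NF-kB and interferon gamma lists 0.24, 0.76, -0.94 and 0.0815, and Cxcl10 1.45. With a minimum of 20 CPM, the 20 named genes kept were 9 in neutrophils, 12 in macrophages, 7 in dendritic cells, 9 in T cells, 8 in NK cells and 9 each in mesothelial, fibroblast and cancer cells. The cause of these differences was not tested, except that each neutrophil cluster alone and a lower CPM minimum differ by construction. The T and NK shares also follow which cells kept a name. With each library clustered alone, 0 and 1043 cells were unnamed, 3116 and 1905 were T-like and 342 and 151 NK-like. At resolution 2, 2303 and 1299 were unnamed, not all of them immune cells, and 1718 and 1963 T-like. Mesothelial-like cells numbered 599 and 538 there, against 1549 and 1174 in the main setting. The main setting had an unnamed cluster of 699 and 732 cells, with 2400 and 1932 T-like. At resolution 0.5, 3118 and 2712 were T-like. Depth limits Il1b in NK cells, with 1 UMI in the library labelled IL1bKO, and all values of fibroblasts, with 218 and 124 cells.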

Other observations

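The tests in this part were all chosen after the results were seen. Fkbp5 and Tsc22d3, which glucocorticoids are known to induce, were both higher in the library labelled IL1bKO in each class described, with Fkbp5 at log2 ratios of 0.41 in cancer-like, 1.07 in T-like, 1.19 in mesothelial-like and 1.56 in macrophage-like cells. Tsc22d3 stood at 2.14 in fibroblast-like and 1.40 in mesothelial-like cells. A glucocorticoid response is a candidate explanation, and 10 other glucocorticoid target genes lay above the high bound of random lists in 4 of 8 classes: macrophage-like (median 0.49), mesothelial-like (0.38), fibroblast-like (0.45) and cancer-like cells (0.20). In neutrophil-like (-0.11), T-like (0.07) and NK-like cells (-0.14) the same genes did not stand out, so the test left this open, and batch coincides with genotype.

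Mertk, higher in macrophage-like cells of the library labelled IL1bKO (log2 1.41), lies on chromosome 2 near Il1b. A chromosome region from another mouse strain, carried along with a targeted allele, may change genes close to Il1b. Of the 171 genes within 5 Mb of Il1b, 58 to 97 were measured per host class, and these had ratios of unusual size in 1 of 7 host classes, dendritic-cell-like cells (68 genes, percentile 97.665). Mertk was also higher in mesothelial-like (1.26) and fibroblast-like cells (1.96) and, by 0.34, in cancer-like cells, an injected line that such a region in the host would not alter. The test left this open, since a region can change single genes such as Mertk.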
